A study of Mus musculus with 36 samples.

How the data were processed

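RNA was measured in an SCN-enriched region of adult C57BL/6J mice after 10 weeks of normal chow or high-fat diet, in 36 libraries. Per the labels' protocols, tissue was taken from fresh brains and frozen at once in liquid nitrogen, RNA was extracted with the RNeasy Micro Kit, and libraries followed the Illumina TruSeq stranded mRNA protocol. Per the submitters' processing notes, the tools were Trimmomatic, TopHat and Cufflinks, with genome builds mm10 and GRCm38; no versions, options or annotation were given there. The deposited values are FPKM, one column per library, in a table per diet with 24883 rows each. The unit is inferred from the values and from the naming of Cufflinks, since the columns have no unit in their headers. No source says whether the authors scaled the values further across libraries or tables. Each diet has its own table, so any difference in how the tables were made cannot be told apart from diet. The sample labels number the time points 0, 4, 8, 12, 16 and 20, and the file headers give the same numbers as zeitgeber time (ZT), which is how they are written here.

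Values were rescaled in each library to sum to 1000000 over the rows shared by both tables, which removes any single factor per library or table, and then transformed as log2(value + 1). A log2 difference is therefore on the log2(value + 1) scale, and it understates the change of genes with low values. Rows with a mean rescaled value of at least 1 over the libraries in a fit were tested. The tables hold 24346 distinct gene symbols, 280 of which stand on several rows (817 rows), and such rows were kept apart. RefSeq gene types were matched by symbol for 24765 rows (99.5%), and coordinates come from GENCODE release M21 on GRCm38. The 13 mitochondrially encoded genes of the RNA quality list had 0 rows in the tables, so that list was not tested.

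Depth in reads cannot be derived from FPKM alone. At 10 genes with a length of 117 nt the values above 0, 2 to 6 per library, were compared with whole multiples of 1 step. The largest step of a preset range that they all met within a tolerance of 0.06 was kept, and all 36 libraries had one. So few values can meet a step by chance, so it is a rough estimate. The step, taken as the FPKM that 1 read gives at that length, ran from 13.8 to 27.3. It gives a rough depth relative to the other libraries and no absolute number of reads. No counting interval or lower limit of detection was computed.

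Rhythms were tested in each diet alone (18 libraries) with a cosine and a sine term of period 24 h in limma 3.58.1 with a mean-variance trend, by the moderated F test, in R 4.3.3. Peak-to-trough fold compares the top and the bottom of the fitted cosine, again on the log2(value + 1) scale, and peak times are those of the fitted cosine. The difference in rhythm between diets was tested with the diet by cosine and diet by sine terms over all 36 libraries. Diet was tested over all time points with time point as a factor, at each time point as a contrast of 12 group means, and across time points with the 5 diet by time point terms. All of these tests were limma tests, two-sided where a direction exists, and p-values were adjusted by the Benjamini-Hochberg method, with genes called at an adjusted p under 0.05. For genes of a list the adjustment was also made over the list alone.

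In all, 27 gene lists were written, and 26 were tested between diets with camera in limma at a preset correlation of 0.01 and again with the correlation estimated from the data. The pathway lists were core clock, SCN peptides and receptors, light- and activity-induced genes, fatty acid oxidation and PPAR targets, cholesterol and fatty acid synthesis, glycolysis, TCA cycle, nuclear-encoded oxidative phosphorylation, NAD and amino acid metabolism, feeding peptides and hormone receptors, inflammation and interferon response, and heat shock and ER chaperones. The cell type and region lists were pan-neuronal, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, ependymal and tanycyte, choroid plexus, meninges and fibroblast, other hypothalamic nuclei, thalamus with cortex and striatum, blood, and pituitary. The RNA quality lists were mitochondrially encoded genes and cytosolic ribosomal proteins. Enrichment of called rhythmic genes in a list was tested with Fisher's exact test, one-sided, against all genes tested in that diet and adjusted over the lists. This test takes genes as independent, which genes measured in the same libraries are not, so its p-values can be too small.

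The tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes named for a rhythm are the core clock list and the 10 named genes with the largest amplitude among those called in a diet. For diet, the rule takes the 10 called genes that rose most and the 10 that fell most, with called list members, and 3 each way at each time point. For rhythm differences it takes the 10 smallest p, or 5 if none is called. Gene models without a name were counted and not named. Other genes named in the text are list members past the threshold over the list alone or examples of their list. Not every list member past that threshold is reported here.

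Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, values as deposited, median-of-ratios size factors, the replicate number as a block, limma without the trend, an F test of any difference among the 6 time points, a rank test of the JTK type, and leaving out each library in turn. Alternatives added after the data were seen were protein-coding genes only, leaving out 3 libraries with at least 10 times the median sum of liver transcripts (for gene lists also with an estimated correlation), leaving out the pair of libraries with the highest score of striatal markers, and 5 tissue scores as covariates (meninges, blood, striatum, oligodendrocyte, liver). A score is the mean z-score of the genes of a list. A further score, made after the data were seen, takes the 15 meninges and fibroblast genes with the smooth muscle genes Acta2, Tagln and Myh11.

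The fits were tested on simulated data with 100 changed genes of each size among the real genes' means and residual SDs. For rhythms under normal chow, 65% of genes with an amplitude of 0.3 (log2) and 94% with 0.6 were recovered, with 6 false calls among 15150 genes. Under high-fat diet 48% and 88% were recovered, with 5 false calls among 15106 genes. For differences in rhythm the shares were 31% and 79% at those sizes. For diet over all time points they were 64% at a log2 change of 0.3 and 92% at 0.6. For diet at a single time point, 48% of changes of 0.6 and 89% of 1.2 were recovered, and for the variation with time point 20% and 73%. The simulated genes varied independently of each other, unlike real ones. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.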

Results

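A region enriched for the suprachiasmatic nucleus (SCN) was profiled by RNA sequencing in mice fed normal chow or a high-fat diet. The SCN holds the central circadian clock of mammals, and transcripts measured in this region cannot be assigned to it alone. Each diet had 18 libraries, 3 at each of 6 times of day, 36 in all. The labels do not say that the 3 libraries of a group came from separate animals, so all p-values measure the spread between samples. Deposited FPKM values summed to 302899 to 432336 per library, with a median of 379447 under normal chow and 380492 under high-fat diet. Reads per library are not stated. Relative depth, roughly estimated from a few short genes, differed 1.97-fold between the shallowest and the deepest library, with a median of 1.01 under normal chow and 1.0 under high-fat diet. Across genes, which are not independent replicates, libraries of the same group correlated at a median Pearson r of 0.980 and libraries of different groups at 0.979. Of 24883 rows, 15173 (61.0%) had a mean rescaled value of at least 1.

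Transcripts made in neighbouring nuclei, 1 of them also made in the SCN, were abundant. Avp, a neuropeptide of SCN neurons and of neighbouring neuroendocrine cells, stood at 1632 ± 722 (SD, n = 18) under normal chow and 1831 ± 1160 (SD, n = 18) under high-fat diet. Oxt, the transcript for oxytocin made in other hypothalamic nuclei, stood at 2325 ± 793 (SD, n = 18) and 2320 ± 1115 (SD, n = 18), and Vip at 30.4 ± 18.8 and 35.6 ± 28.8. Hcrt, a peptide of the lateral hypothalamus, ranged from 0.979 to 683 between libraries. The first replicate of normal chow at ZT 0 had 1890 for Alb, the transcript of the liver's serum albumin, against a median of 15.2 over the libraries. All values are on the scale of FPKM rescaled to 1000000 per library.

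The first comparison asked which transcripts followed a 24 h rhythm under normal chow. Dbp, a clock output transcription factor (chromosome 7, 45705088 to 45710203, GRCm38), rose and fell 2.53-fold and peaked at ZT 9.62 ± 0.305 (SE, n = 18 libraries; limma adjusted p = 2.06e-05). Nr1d1, a clock repressor, had a 1.47-fold rhythm with a peak at ZT 6.75, and Ciart, another clock repressor, a 1.59-fold rhythm with a peak at ZT 8.67. These 3 of the 25 core clock genes passed over all genes (0.211 expected, Fisher's exact test adjusted p = 0.0160), and 6 passed when adjusted over the list alone. The additional ones were Cry1 at ZT 13.0, Nr1d2 at ZT 13.4 and Arntl, the activator that works against the repressors, at ZT 22.8. The fitted folds of Per1 (1.33) and Per2 (1.32) did not pass in either way.

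Larger rhythms under normal chow lay outside the clock list. Fabp7, a brain fatty acid binding protein of astrocytes (chromosome 10, 57784881 to 57788450, GRCm38), swung 3.82-fold around 221 ± 101.9 (SD, n = 18) with a peak at ZT 3.75, and Plin4, a lipid droplet coat protein, 3.84-fold with a peak at ZT 15.9 (limma adjusted p = 8.40e-05 and 0.00281). Both belong to the list of fatty acid oxidation and PPAR targets, where 3 of 33 genes passed over all genes with Acot1 (0.279 expected, Fisher's exact test adjusted p = 0.0240), and 8 when adjusted over the list alone. The heat shock and ER chaperone list had 9 of 31 genes called (0.262 expected, Fisher's exact test adjusted p = 7.68e-11) and 24 when adjusted over the list alone. Genes of this list were correlated (estimated correlation 0.32 in the diet fit), so they do not count as independent. In that list Hspa1b (2.32-fold) peaked at ZT 19.1, Hspa5 (1.48-fold) at ZT 19.7 and Hsph1 (1.54-fold) at ZT 21.2. The cold-inducible RNA-binding proteins Rbm3 (1.95-fold) and Cirbp (1.66-fold) of the list peaked at ZT 10.9 and ZT 9.30. Other called genes of large amplitude were Kirrel2 (2.42-fold, ZT 15.7), Angptl2 (2.35-fold, ZT 10.2), Plekhf1 (2.16-fold, ZT 13.8), the oligodendrocyte gene Opalin (2.09-fold, ZT 5.63) and Cdh19 (2.07-fold, ZT 16.2). Lum, a proteoglycan of connective tissue, swung 2.47-fold with a peak at ZT 12.3. A mean score of 18 meningeal and smooth muscle transcripts peaked at ZT 12.0 in the same libraries.

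In all, 128 of 15150 genes were called rhythmic under normal chow, 119 of them named gene models, and 2761 (18.2%) had an unadjusted p under 0.05. Their median fold was 1.47 (1.19 to 3.84), and 18 peaked at ZT 0 to 6, 22 at ZT 6 to 12, 33 at ZT 12 to 18 and 55 at ZT 18 to 24. The count was 262 with median-of-ratios size factors, 50 for any difference among time points, 21 with 5 tissue scores as covariates and 204 without the 3 libraries rich in liver transcripts. It was 0 with a rank test of the JTK type (2291 at an unadjusted p under 0.05, smallest adjusted p = 0.0665). Leaving out the third replicate at ZT 16 gave 48, and the highest count with a library left out was 162.

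**Figure D1:**
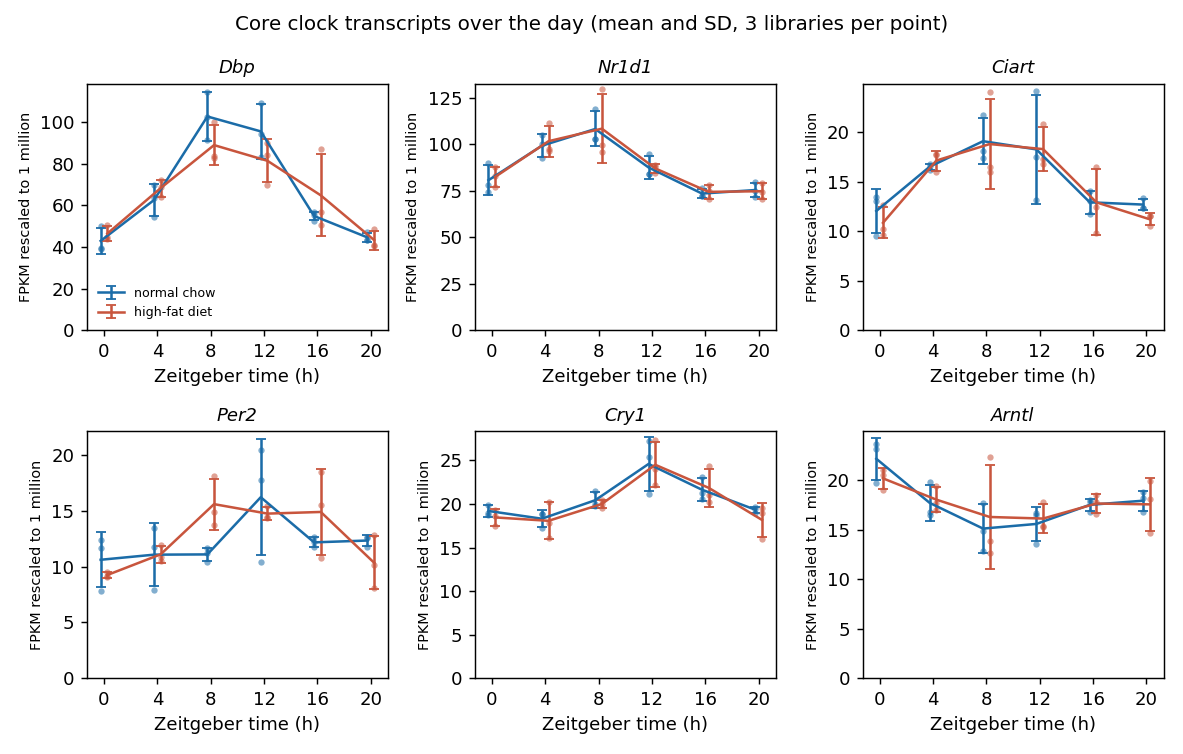
FPKM rescaled to 1000000 (vertical axes, from 0) against zeitgeber time in hours for 6 core clock transcripts. Points are libraries, lines join the means of 3 libraries and bars are SDs, in blue for normal chow and red for high-fat diet. Dbp reached its highest mean at ZT 8 in both diets.

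Under high-fat diet the same question gave a shorter list. Dbp swung 2.08-fold with a peak at ZT 9.45 ± 0.452 (SE, n = 18; limma adjusted p = 0.00279), Nr1d1 1.47-fold with a peak at ZT 6.53, and Fabp7 2.20-fold with a peak at ZT 2.20. Mfsd2a, a lipid transporter of the blood-brain barrier, had the smallest p, with a 2.03-fold rhythm peaking at ZT 15.9 (limma adjusted p = 1.12e-04). Hif3a (2.81-fold, ZT 13.3), Kirrel2 (2.78-fold, ZT 15.7), the ER chaperone partner Sdf2l1 (1.76-fold, ZT 21.1), Gpt2 (1.48-fold, ZT 15.0), Klf15, a glucocorticoid-induced transcription factor (1.48-fold, ZT 13.9), and Hmgb3 (1.44-fold, ZT 7.77) made up the remaining named genes. Of the core clock list 2 genes passed over all genes (0.0182 expected, Fisher's exact test adjusted p = 0.00387) and 7 when adjusted over the list alone, Per1 at ZT 10.9 and Per2 at ZT 11.4 among them. Of the chaperone list 1 gene passed over all genes and 8 when adjusted over the list alone.

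Counted over all genes, 11 of 15106 were called under high-fat diet, 10 of them named, and 1305 (8.64%) had an unadjusted p under 0.05. Of the genes called in each diet, 8 were shared, against 0.0939 expected of independent lists. Of the 128 genes called under normal chow, 79 (61.7%) had a fitted peak within 3 h under high-fat diet. Unrelated peaks spread evenly over the day would give 25%, but 55 of the 128 peaked at ZT 18 to 24 under normal chow. The genes are also not independent, so the 25% is no tested chance level. Of the same 128, 44 had an unadjusted limma p under 0.05 under high-fat diet and 120 a lower amplitude there. Of the 11 genes called under high-fat diet, 8 had a lower amplitude under normal chow. Genes picked for passing in a diet favour high amplitudes in it, so these counts do not test smaller rhythms. The median residual SD was 0.166 under normal chow and 0.206 under high-fat diet. The high-fat count was 5 with no filter, 2 for any difference among time points, 2 with the rank test, 1 with 5 tissue scores as covariates and 4 to 13 with a library left out, lowest without the first replicate at ZT 4 or at ZT 8 or the second at ZT 16.

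**Figure D2:**
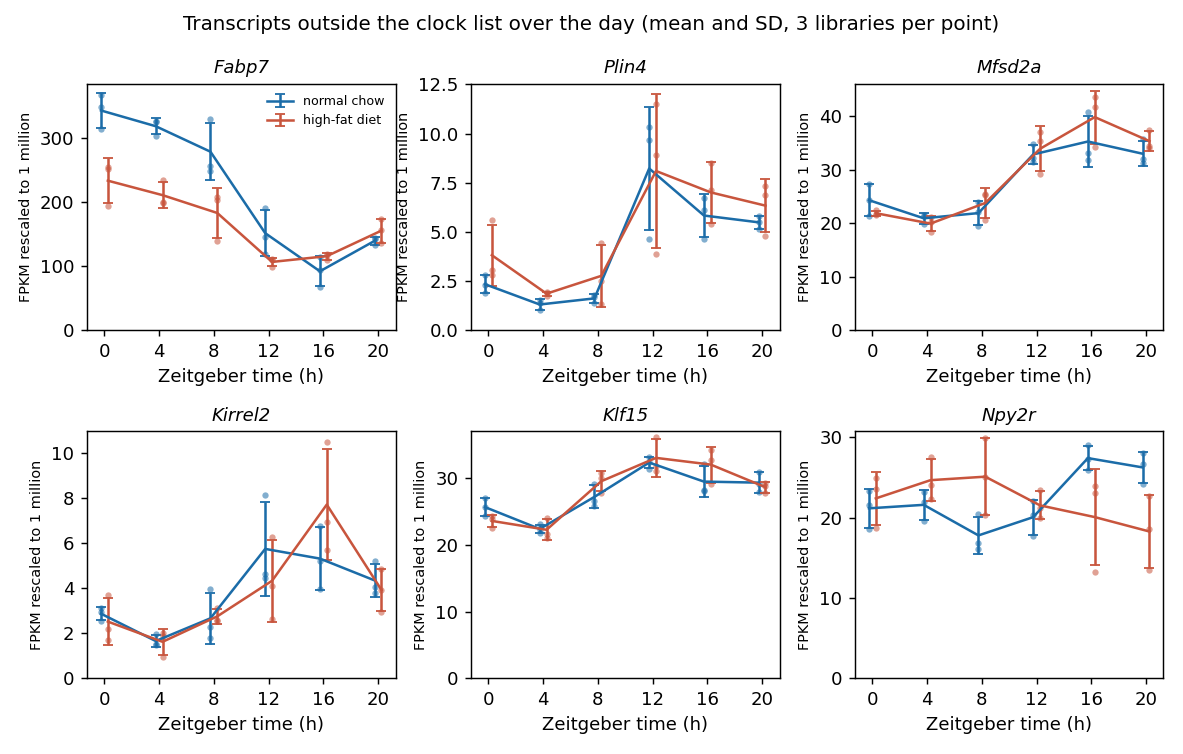
FPKM rescaled to 1000000 (vertical axes, from 0) against zeitgeber time in hours for 6 transcripts outside the core clock list. Points are libraries, lines join the means of 3 libraries and bars are SDs, in blue for normal chow and red for high-fat diet. Mfsd2a and Plin4 had fitted peaks at ZT 15.9 to 16.4 in both diets, and the fitted peaks of Npy2r lay at ZT 18.9 under normal chow and ZT 6.09 under high-fat diet.

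A rhythm called under a single diet is not a difference, so the difference itself was tested. Peak times of the 5 clock genes that passed over the list alone in both diets (Dbp, Nr1d1, Ciart, Cry1 and Nr1d2) differed by a median of 0.221 h (SD 1.38), the largest shift of these being that of Nr1d2 from ZT 13.4 to ZT 10.1 (unadjusted p = 0.0697). By limma 0 of the 25 core clock genes passed the test of a difference in rhythm, over all genes or over the list alone, and 1, the kinase Csnk1d, had an unadjusted p under 0.05 (0.0199). Grem1, Bcl7c, Cast, Npy2r and Fabp7 had the smallest p-values and none was called over all genes (limma adjusted p = 0.357 for each). Adjusted over the list alone, 2 of these passed: Fabp7, with 3.82-fold under normal chow and 2.20-fold under high-fat diet (adjusted p = 0.0136), and Npy2r, a receptor for neuropeptide Y (adjusted p = 0.00385). Both had been named for their small p, and the adjustment over a list allows neither for that nor for the number of lists. In the meninges and fibroblast list 11 of 15 genes passed over the list alone, with fitted peaks near ZT 12 under normal chow and near ZT 3 under high-fat diet, as for Lum (ZT 12.3 and ZT 3.29) and Dcn (ZT 11.9 and ZT 2.98). For a rhythm within a diet, 7 of the 15 passed over the list alone under normal chow and 0 under high-fat diet. Over all genes limma called 0 of 15173 differences in rhythm, with 2004 (13.2%) at an unadjusted p under 0.05.

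**Figure D3:**
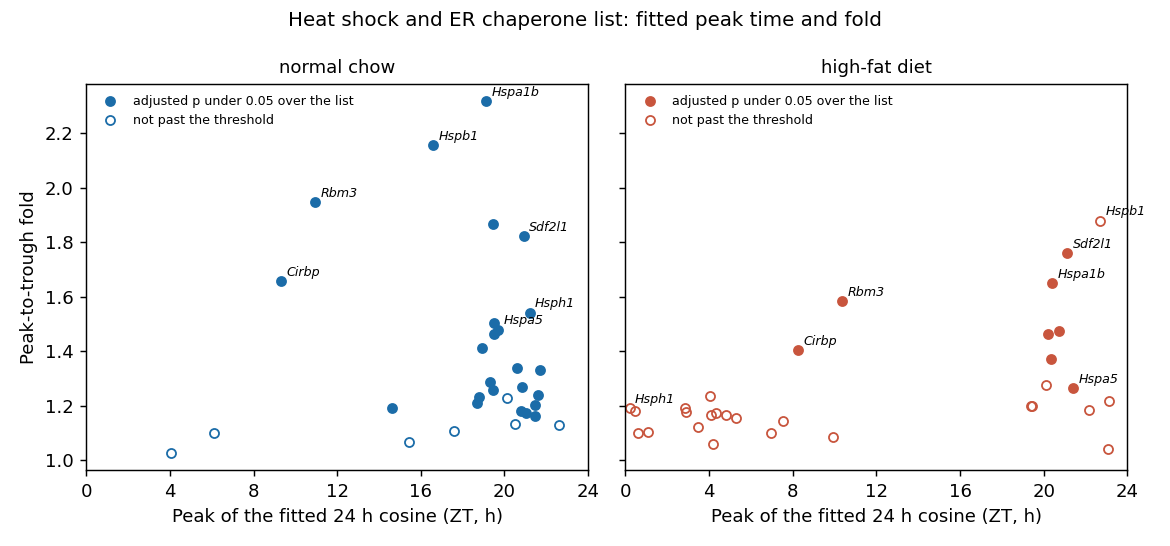
Peak-to-trough fold (vertical axis) against the fitted peak time in zeitgeber hours (horizontal axis) for the 31 tested genes of the heat shock and ER chaperone list, under normal chow on the left and high-fat diet on the right. Filled points passed when adjusted over the list alone, 24 under normal chow and 8 under high-fat diet. Rbm3 and Cirbp peaked at ZT 8.27 to 10.9, apart from the other filled points.

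The comparison of the diets over all time points asked which transcripts high-fat feeding changed whatever the hour. Rbm3, a cold-inducible RNA-binding protein (chromosome X, 8138975 to 8145880, GRCm38), was lower under high-fat diet, at 122 ± 25.1 against 170 ± 44.8 (SD, n = 18, the time of day included), a log2 change of -0.46 ± 0.056 (SE; limma adjusted p = 3.51e-05), and its mean was lower at 6 of 6 time points. C4b, a complement component (chromosome 17, 34728380 to 34743882, GRCm38), was higher, at 29.6 ± 7.11 against 19.5 ± 4.69 (SD, n = 18), a log2 change of 0.59 ± 0.091 (SE; limma adjusted p = 0.00260), again at 6 of 6 time points. C4a, a near-identical copy of C4b that was looked up after the result was seen, had a log2 change of 0.32 ± 0.078 (adjusted p = 0.586), and since reads of the pair can be assigned to either copy, the level of C4b alone is uncertain. These were the 2 genes called of 15173, with 389 (2.56%) at an unadjusted p under 0.05, 165 higher and 224 lower. Cirbp, the relative of Rbm3, had a log2 change of -0.16 ± 0.051, which did not pass over its list (adjusted p = 0.0605).

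C4b belongs to the inflammation and interferon list. Of its 24 tested genes 23 had a positive log2 change, with a mean of 0.15, and the list was higher under high-fat diet by camera (adjusted p = 2.96e-17, and adjusted p = 0.0303 with an estimated correlation). With diet reassigned within time points, camera called a median of 8 lists at the preset correlation, so its adjusted p-values there are too small. Over all genes 1 member passed, and 4 when adjusted over the list alone: C4b, Socs3 (0.30 ± 0.062), Stat3 (0.19 ± 0.039), the transcription factor of leptin and interleukin-6 signalling, and the acute-phase inhibitor Serpina3n (0.22 ± 0.071). The microglia list was higher by camera (adjusted p = 1.34e-09) with 19 of 19 genes positive and 1, the lysosomal protease Ctss (0.23 ± 0.068), past the threshold over the list alone, but had an adjusted p = 0.269 with an estimated correlation. Positive mean changes were also seen for the microglia, blood, endothelial and mural, and meninges and fibroblast lists, among others. Those of the pan-neuronal, oligodendrocyte and other hypothalamic lists were negative. No fit of the inflammation list with tissue scores was run.

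**Figure D4:**
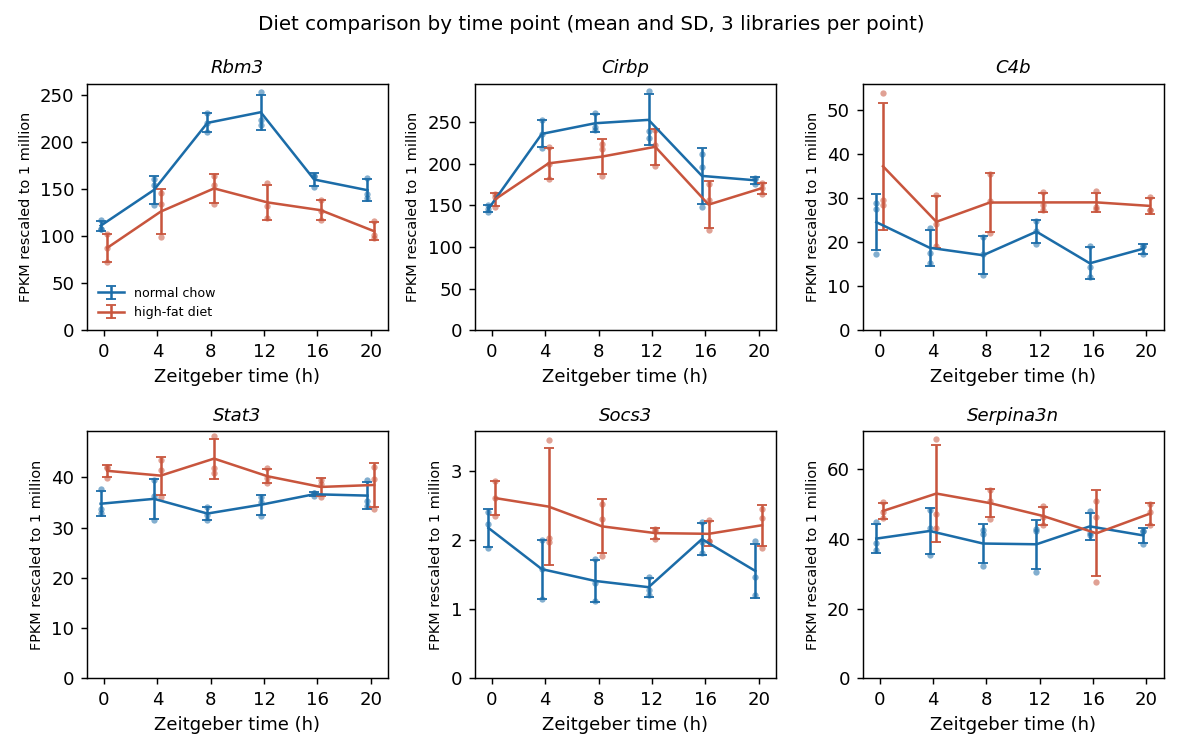
FPKM rescaled to 1000000 (vertical axes, from 0) against zeitgeber time in hours for Rbm3 and its relative Cirbp and for 4 genes of the inflammation list. Points are libraries, lines join the means of 3 libraries and bars are SDs, in blue for normal chow and red for high-fat diet. Mean Rbm3 was lower and mean C4b higher under high-fat diet at 6 of 6 time points.

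The metabolic lists were compared in the same way. The fatty acid oxidation and PPAR list did not pass (camera adjusted p = 0.0522), and 0 of its 33 genes were called over all genes by limma, with 7 at an unadjusted p under 0.05. Genes that passed when adjusted over the list alone went both ways and included Angptl4, a secreted inhibitor of lipoprotein lipase (0.27 ± 0.072), Fabp7 (-0.29 ± 0.093) and Acot1 (-0.17 ± 0.055). Without the 3 libraries rich in liver transcripts the list passed (adjusted p = 0.00166), but not with an estimated correlation (adjusted p = 0.476, and 0.644 over all libraries). Cholesterol and fatty acid synthesis was lower by camera (adjusted p = 3.56e-04, and adjusted p = 0.558 with an estimated correlation), with 23 of 30 genes negative, 0 past the limma threshold over the list alone and 2 at an unadjusted p under 0.05. Nuclear-encoded oxidative phosphorylation was lower with 33 of 36 genes negative and a mean of -0.04 (adjusted p = 3.23e-04, and adjusted p = 0.644 with an estimated correlation). Glycolysis, the TCA cycle, NAD and amino acid metabolism, core clock, SCN peptides and receptors, light- and activity-induced genes, feeding peptides and hormone receptors, and heat shock and ER chaperones did not pass (camera adjusted p from 0.282 to 0.835). Socs3 was the 1 gene of the feeding list that passed over its list alone.

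Several lists of other cell types and regions were called with the preset correlation and none of them with an estimated one over all libraries. Blood transcripts were higher, with 9 of 9 genes positive and a mean of 0.46 (adjusted p = 1.76e-08, and adjusted p = 0.0995 with an estimated correlation), as for Hba-a1 at 1729 ± 768 against 1317 ± 780 (SD, n = 18). Endothelial and mural genes were 20 of 20 positive (adjusted p = 1.88e-12, and adjusted p = 0.159 with an estimated correlation), and meningeal and fibroblast genes 15 of 15 (adjusted p = 1.65e-05, and adjusted p = 0.539 with an estimated correlation). Astrocyte genes were 14 of 15 positive (adjusted p = 0.00285, and adjusted p = 0.567 with an estimated correlation) and pituitary genes 5 of 7 (adjusted p = 0.0298, and adjusted p = 0.539 with an estimated correlation). Oligodendrocyte genes were lower, 15 of 17 negative (adjusted p = 0.0208, and adjusted p = 0.862 with an estimated correlation). Genes of other hypothalamic nuclei were lower too, 21 of 27 negative (adjusted p = 0.00786, and adjusted p = 0.357 with an estimated correlation). By limma 0 genes of these lists passed over their list alone, while 4 blood, 7 endothelial and mural, 1 astrocyte, 1 oligodendrocyte, 1 pituitary, 1 other hypothalamic and 0 meningeal genes had an unadjusted p under 0.05. Pan-neuronal, oligodendrocyte precursor, ependymal and tanycyte, choroid plexus, thalamus with cortex and striatum, and cytosolic ribosomal protein lists did not pass (adjusted p from 0.348 to 0.849). By camera with the preset correlation 11 of 26 lists were called, and 1, inflammation, with an estimated correlation. Without the libraries rich in liver transcripts 2 were called with an estimated correlation, inflammation and blood (adjusted p = 0.0381 and 0.0192). With the preset correlation and without those libraries, the meninges, other hypothalamic and pituitary lists lost their call (adjusted p = 0.0789, 0.123 and 0.0819). Without the striatal pair the astrocyte list did (adjusted p = 0.0617).

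The diets were also compared at each time point, which asks when in the day they differed. At ZT 12, Rbm3 stood at 136 ± 18.4 under high-fat diet and 232 ± 18.7 under normal chow (SD, n = 3 each), a log2 change of -0.77 ± 0.125 (limma adjusted p = 0.0206). It was the only gene called at a time point by limma, and 0 were called when all 6 contrasts were adjusted together. Stat3 at ZT 8 had a log2 change of 0.40 ± 0.087, and Chga, a granin of secretory vesicles, had -0.57 ± 0.103 at ZT 16 and was picked after its value was seen, and neither passed (limma adjusted p = 0.273 and 0.112). Genes at an unadjusted p under 0.05 numbered 592 at ZT 0, 227 at ZT 4, 2442 at ZT 8, 148 at ZT 12, 1630 at ZT 16 and 605 at ZT 20. In the second high-fat replicate at ZT 8 the first principal component was 46.2, against -5.16 and 3.55 in the other replicates. This unadjusted count at ZT 8 was not taken without that library, so the counts do not show when the diets differed most. A diet change that varied with time point was called for 0 genes by limma, with 773 (5.09%) at an unadjusted p under 0.05, and Rbm3 was not among those called (adjusted p = 0.720). The call of Rbm3 at ZT 12 was lost in 7 of 46 alternatives, with an adjusted p of 0.527 without the first high-fat replicate at ZT 12. The calls at single time points numbered 1100 without the first high-fat replicate at ZT 8, 1 without the second and 1066 with 5 tissue scores as covariates.

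**Figure D5:**
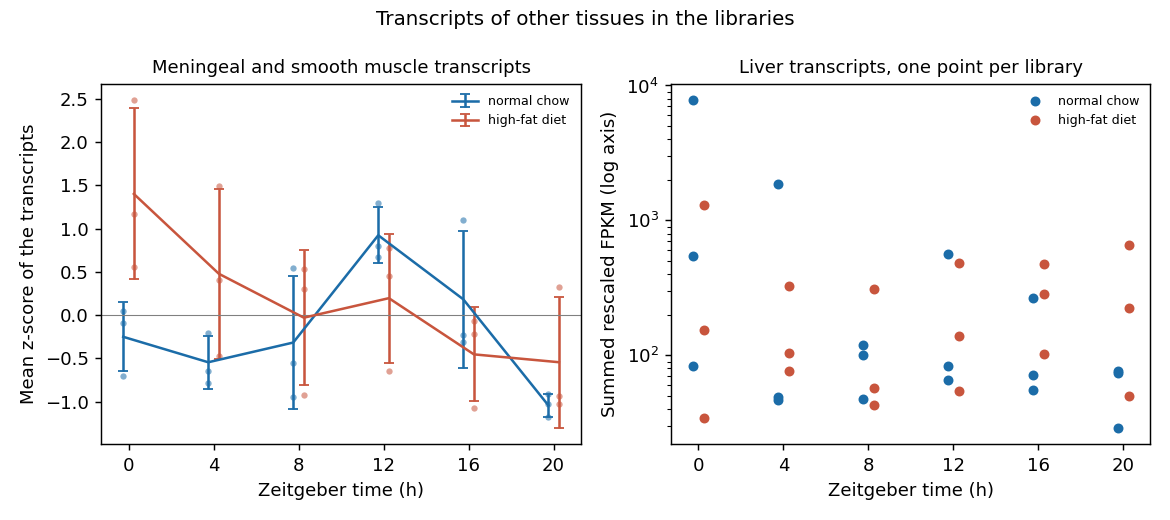
Left, the mean z-score of 18 meningeal and smooth muscle transcripts (vertical axis) against zeitgeber time in hours, with points for libraries, lines joining the means of 3 libraries and bars for SDs. Right, the sum of 23 liver transcripts per library on a log axis, in FPKM rescaled to 1000000. Blue is normal chow and red is high-fat diet, and the liver sum ran from 29.1 to 7802.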

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

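In this part, the tests of rhythm size, of warmer tissue and of the meningeal score were chosen only after the results were seen. For the regroupings of the libraries, the bounds were written before the runs, except for the meningeal score and the squared amplitude. The gap in rhythm counts and the inflammation list were themselves picked from the results. Groups of 3 libraries were not tested for a library far from the others. A difference between the diets in the 24 h rhythm, tested directly and adjusted over the list alone, singled out 11 of 15 genes of the meninges and fibroblast list, 5 genes of the endothelial and mural list (Cdh5, Itm2a, Acta2, Tagln and Myh11), 2 of the choroid plexus list (Kl and Kcnj13), 1 of the fatty acid oxidation list (Fabp7) and 1 of the feeding list (Npy2r). None of them passed over all genes, and adjustment over a list makes no allowance for the number of lists.

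The first pattern is the different fitted timing of meningeal and smooth muscle transcripts. Their mean score had a fitted peak at ZT 12.0 under normal chow and at ZT 2.77 under high-fat diet. Tested in each diet alone, 7 of 15 meninges and fibroblast genes passed over the list alone under normal chow and 0 under high-fat diet. The high-fat peak is thus that of a fit and not of an established rhythm. The highest high-fat score, 2.49, was that of the third replicate at ZT 0, a library rich in liver transcripts. Diet was reassigned within time points, and 1 of 100 regroupings, the real one, gave a difference as large (1.18, highest other 1.16), but the score was picked for its difference, so this excludes nothing. Within groups of the same diet and hour the transcripts rose and fell together, with a mean correlation of their deviations of 0.724 against 0.121 for 360 random genes, which is consistent with uneven amounts of meninges in the dissected pieces. Shared regulation of these transcripts could give the same correlation and was not tested apart, and whether amounts of tissue differed by hour and diet by accident of dissection stays open. A rhythm of the tissue itself that high-fat diet shifts was not tested.

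The second pattern is the lower count of rhythmic genes under high-fat diet, 11 against 128. A gap as large, in either direction, came from 8 of 100 reassignments of diet within time points (highest other 1699), so chance cannot be excluded. Gaps that large may reflect a structure of the samples, which was not tested. Over the 14996 genes tested in both diets, giving normal chow genes the residual spread of the high-fat libraries lowered their count from 134 to 37, and the reverse raised the high-fat count from 11 to 216; the 37 passed the bound of 3 times the high-fat count set beforehand against spread, but only just, and a bound from a simulated setting excludes nothing, so a larger spread stays open. Excess squared amplitude was lower under high-fat diet (ratio 0.476), but 16 of 100 reassignments gave a difference as low, in a statistic that replaced an unstable ratio, and with 5 tissue scores the high-fat count was 1 and the normal chow count 21, which met the bound against tissue makeup but in a test that removed most calls of both diets. Spread, smaller rhythms and tissue makeup cannot be told apart here.

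The third pattern is the change of Rbm3 and C4b with diet. Chance is unlikely for the pair, since 1 of 100 reassignments of diet, the real one, gave 2 called genes (highest other 0). That is the lowest share 100 reassignments can give. With scores of blood, vessel, meninges and microglia genes as covariates, Rbm3 kept 107% of its change and its call (adjusted p = 1.04e-05), which argues against more of these tissues as its cause, while C4b kept 80.1% and lost its call (0.59 ± 0.091 to 0.47 ± 0.089, adjusted p = 0.109), because its change shrank, so part of it may follow those tissues. With the liver score as a covariate the change of C4b was 0.585 (limma adjusted p = 6.00e-04), which argues against liver RNA as its cause but does not exclude it. The median change of 22 liver transcripts was 0.02, though the median liver sum was 146 under high-fat diet and 79.7 under normal chow. Warmer tissue, a candidate explanation for lower Rbm3, was looked for in Hspa1a, Hspa1b, Hsph1 and Dnajb1, whose mean change was 0.0028 ± 0.060 where their daily proportion to Rbm3 would give 0.385; the bound first set would have excluded it, but that proportion is an assumed profile, so the bound was revised and the explanation stays open, as does diet itself.

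The regroupings of the other results, with the real value first, were as follows. For rhythms under normal chow, 1 of 100 assignments of the time labels, the real one, gave 128 or more called genes (highest other 0). Chance is thus unlikely for that count, though 1 of 100 is the lowest share possible here. Under high-fat diet 2 of 100 gave 11 or more, the real one included, and the highest other called 33. Chance is thus unlikely for the high-fat count but not excluded. For the 0 called differences in rhythm and the 0 called variations of diet with time point, 100 of 100 gave as many (highest other 1 and 53), as any regrouping must, so this says nothing about chance. The 53 may reflect a structure of the samples, which was not tested. For gene lists, 28 of 100 gave 11 or more called lists with the preset correlation (highest other 16), so chance cannot be excluded for that count. The median of the other regroupings was 8 lists, so the preset correlation called many lists without the real diet labels. For the inflammation list with an estimated correlation, 1 of 100, the real one, gave a camera -log10 p of 2.93 (highest other 1.53). That comparison makes no allowance for this list being the 1 called of 26. With an estimated correlation 6 of 100 regroupings, the real one included, called 1 list or more, so chance cannot be excluded for the call. At single time points the 10 splits of 6 libraries are too few to give a share under 0.05: 10 of 10 gave the 0 genes called at ZT 0, 4, 16 and 20 (highest other 0) and at ZT 8 (highest other 1), and 2 of 10 the 1 gene called at ZT 12 (highest other 1).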

How the results depend on the processing

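The protein-coding, liver-rich, striatal and tissue score alternatives, and the test that shuffles replicate numbers, were chosen only after the data were seen. Rbm3 and C4b kept direction and call between diets in all 47 alternatives (log2 change -0.49 to -0.44 and 0.52 to 0.62, highest adjusted p 1.07e-04 and 0.0298), and 0 differences in rhythm were called in the 46 run for them. A fit with 4 tissue scores, not among the 47, ended the call of C4b (adjusted p = 0.109). Among genes named for a rhythm, 152 of 194 values kept their call under other settings and 249 of 360 with a library left out. The FPKM scale gives no counts, so what depth limits could not be worked out beyond the filters tried. The cause of the moves below was not tested.

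For genes with a 24 h rhythm under normal chow the count was 262 with median-of-ratios size factors, 50 for any difference among time points, 0 with the JTK-type rank test, 204 leaving out libraries rich in liver transcripts and 21 with tissue scores as covariates. With a library left out it ran from 48 to 162. It moved by over 1.5 times without NC replicate 2 at ZT 0 (78), replicates 2 and 3 at ZT 4 (72 and 60), replicates 1, 2 and 3 at ZT 8 (60, 60 and 74), replicates 1, 2 and 3 at ZT 16 (60, 67 and 48) and replicate 2 at ZT 20 (50). For genes with a 24 h rhythm under high-fat diet the count was 5 with no filter, 2 for any difference among time points, 2 with the JTK-type rank test and 1 with tissue scores as covariates. With a library left out it ran from 4 to 13, and it moved by over 1.5 times without HFD replicates 1 and 2 at ZT 0 (7 and 6), replicates 1, 2 and 3 at ZT 4 (4, 6 and 5), replicate 1 at ZT 8 (4), replicates 2 and 3 at ZT 12 (5 and 5), replicates 1 and 2 at ZT 16 (6 and 4) and replicate 3 at ZT 20 (5).

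For genes that differ between diets over all time points the count was 7 with tissue scores as covariates and 2 to 3 with a library left out. For genes that differ between diets at each time point it was 2 with no filter, 0 with values as deposited, 2 leaving out libraries rich in liver transcripts and 1066 with tissue scores as covariates. With a library left out it ran from 0 to 1100: 1100 without HFD replicate 1 at ZT 8, 0 without NC replicate 2 or HFD replicates 1 or 3 at ZT 12, and 2 without NC replicate 2 at ZT 0, NC replicate 1 at ZT 12, HFD replicates 2 or 3 at ZT 0 or HFD replicate 1 at ZT 16. For genes whose diet difference varies with time point it was 1 leaving out libraries highest in striatal markers, and 0 to 1 with a library left out, 1 without NC replicate 2 at ZT 0 or replicate 3 at ZT 12. Genes whose rhythm differs between diets stayed at 0 to 0 with a library left out. Lists called numbered 1 with an estimated correlation, and 2 with it when leaving out libraries rich in liver transcripts.

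The mean log2 change of 5 lists not called in either fit turned sign. Leaving out libraries rich in liver transcripts, with either correlation, gave -0.0072 for the list light- and activity-induced genes, -0.0416 for the list oligodendrocyte precursor (-0.0029 with median-of-ratios size factors) and -0.0073 for the list thalamus, cortex and striatum. Leaving out libraries highest in striatal markers gave -0.0065 for the list light- and activity-induced genes, 0.0024 for the list TCA cycle, 0.0038 for the list heat shock and ER chaperones and -0.0012 for the list thalamus, cortex and striatum.

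Replicate numbers were not taken as pairing, since the labels give them no shared animal or batch. Deviations of the libraries from their group means were correlated between libraries of different groups. Nor did every same-numbered pair correlate over 0.1 in these deviations (mean 0.032, -0.575 to 0.641, and -0.016 for different numbers). Still, the deviations of 23 of 36 libraries correlated best on average with those of their own number, against a mean of 12.3 when numbers were shuffled within groups (7 of 1000 shuffles gave as many). This is a hint from the data and not the design. With the replicate block the counts were 90 rhythmic genes under normal chow, 7 under high-fat diet, 0 differences in rhythm, 2 genes between diets over all time points, 1 at single time points, 0 that varied with time point, 11 lists, and 6 and 11 core clock genes over the list alone under normal chow and high-fat diet, with a peak difference of 0.221 h.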

Other observations

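The tests of the liver list in this part, and the library at ZT 8 given at its end, were chosen only after the data were seen; no explanation is offered here. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, had a 1.68-fold rhythm with a peak at ZT 14.4 under normal chow (n = 18; limma adjusted p = 0.00653) and a fitted 1.64-fold rhythm at ZT 13.5 under high-fat diet. Sgk1, a glucocorticoid-induced kinase, had fitted swings of 3.14-fold at ZT 13.7 and 3.01-fold at ZT 13.1, past the threshold over the feeding and hormone list alone in both diets, and Fkbp5, a co-chaperone of the glucocorticoid receptor, 1.37-fold at ZT 16.2 under normal chow. Of that list 1 gene passed over all genes under normal chow and 4 when adjusted over the list alone (enrichment by Fisher's exact test, adjusted p = 0.535). None of these 3 genes differed in rhythm between diets in the direct test.

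Single genes of other lists passed a threshold as well. Cholesterol synthesis genes Msmo1, Mvd, Dhcr7 and Insig1 peaked at ZT 6.68 to 6.86 under normal chow, past the threshold over the list alone, with folds of 1.17 to 1.36. Ifit3 (1.91-fold) and Nfkbia (1.60-fold), from the inflammation list, were called over all genes under normal chow, both with a peak at ZT 13.6. Rasl11b, from the list of SCN peptides and receptors, swung 1.76-fold with a peak at ZT 4.46 and was called under normal chow.

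Transcripts typical of liver stood out in single libraries. All 23 genes of a liver list, 12 of which had not been looked at when the library was noticed, were highest in the first replicate of normal chow at ZT 0, where their sum was 7802 against a median of 101.7 over the libraries. The first replicate of normal chow at ZT 4 had 18.3 times the median and the third replicate of high-fat diet at ZT 0 had 12.8 times. The median sum was 79.7 under normal chow and 146 under high-fat diet, and a two-sided permutation test of the mean log2 sums with 100000 resamples gave p = 0.755. In the second replicate of high-fat diet at ZT 8, Avp stood at 234 against 1809 and 1459 in the other replicates of its group, Oxt at 372 against 2782 and 2009, and the first principal component at 46.2 against -5.16 and 3.55. The count of genes called between diets over all time points was 2 without that library.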
